A study of Schmidtea mediterranea with 4 samples.

How the data were processed

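RNA of Schmidtea mediterranea, an asexual planarian flatworm of clone W4, was compared on Agilent 2-colour oligonucleotide arrays. Per the labels, animals were kept at 20 °C and fed double-stranded RNA against runt-1 or, as a control, unc-22, every 4 days for 12 days, and RNA was taken 5 days after the last feeding with 10 animals per replicate. The labels name 4 samples, which served as the 4 groups: whole animals 5 min, 9 h and 24 h after amputation, and sorted X1 cells (the cell fraction that holds dividing neoblasts, the planarian stem cells) 9 h after amputation. Each sample came with 3 arrays, which the labels describe as 3 biological replicates combined under a single sample. Array numbers here follow file order and only name an array. Per the labels, the runt-1 RNAi RNA carried Cy5 and the unc-22 RNAi RNA carried Cy3 on every array, so no dye swap balances a dye effect in a group's ratio. A dye effect common to all arrays cancels in a difference between groups.

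The deposited scanner files hold spot intensity values of both dyes (foreground mean and local background median), made by Agilent Feature Extraction with linear and LOWESS dye normalization and spatial detrending, per the file headers. They also hold processed intensity signals and a log10 ratio of Cy5 over Cy3, per the file headers, and marks for spots above background, saturated or uneven. The authors deposited a table of their own comparisons, with a log2 fold change, a t score, a raw p-value and an adjusted p-value for each group. The submitters' processing notes name limma for this table and give no version. The design of the authors' fit is not given in the sources used here.

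Each array carried 45220 spots, of which 1417 were control spots and 43803 were probes of 60 bases. Probes are identified by contig names. The files pair 0 of them with a gene name or a homolog, and no reference was used here. The 17 lists of genes and cell type markers fixed beforehand were therefore void, since 0 of them could be matched, and the runt-1 transcript is not reported by name. Probe identifiers are used as the files give them, and what each probe detects is left open. A subset of 3322 probes has a name ending in r, and 3314 of these are the exact reverse complement of the probe with the name without r.

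Intensities were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots and spots the scanner marked as uneven given weight 0. Both were then left out. Probes were kept where they were well above background in either channel on at least 3 of the 12 arrays, which left 37752 and removed 6051. The log2 ratio of runt-1 RNAi over unc-22 RNAi was fitted with a mean per group over all 12 arrays, and each mean was tested against 0 with limma's moderated test. Differences between groups were contrasts in the same fit. The control channel was compared between groups after Aquantile normalization between arrays, which keeps the within-array ratios. The same contrasts were repeated on the runt-1 RNAi channel after the data were examined. Adjusted p-values are from limma with the Benjamini-Hochberg method, with a threshold of 0.05. Where a group had no array well above background for a probe, its fold is given as a lower bound against the lowest signal well above background on each array, and such bounds stay open to dye bias.

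Sets of probes were defined from the control channel: the 200 with the smallest p among those higher in X1 cells than in whole animals, and the 100 with the smallest p among those higher after amputation. Each set was made from arrays of groups other than the group tested, with exceptions stated beside the values. Sets were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, over 8 set and group combinations. Probes are named by a rule fixed before the data were examined: since no probe has a gene name, at most 2 that rose and 2 that fell per comparison, taken by size of change among those past the threshold whose arrays did not overlap (for ratios, with the same sign on all 3 arrays), or by moderated t where fewer than 5 passed. Probes named outside this rule are said to have been chosen after their values were seen.

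The fits were tested on simulated values with the spread of the real probes, with 200 of 37752 probes changed. In the simulated ratios, 77.6%, 94.0%, 82.1% and 82.1% of the probes changed 2-fold were called at 5 min, 9 h, 24 h and in X1 cells, and 55.2%, 62.7%, 59.7% and 65.7% of those changed 1.5-fold, with 9, 8, 9 and 16 false calls. The 16 false calls in the simulated X1 cells came beside 44, 55 and 64 true calls at 1.5-fold, 2-fold and 4-fold. They are therefore no measure of false calls among the calls in the real X1 cells. In the simulated difference between 24 h and 9 h, 64.2% of the probes changed 2-fold were called. The simulated spread was independent between probes, which that of the real arrays was not. For each probe it was also the same in every group. The median SD between real arrays was 0.24, 0.12, 0.16 and 0.075 at 5 min, 9 h, 24 h and in X1 cells. The simulated shares called therefore do not describe the power of each real group. Slide and scan session were tested as batches: 12 arrays lay on 6 slides, 2 per slide, in 2 scan sessions. Alternatives were the background correction, the offset, the scanner's processed signals, scaling between arrays, the filter on dim probes, slide and session terms, array weights, the arrays in the fit, each array left out in turn, and the authors' deposited table. With 3 arrays per group, the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.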

Results

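The study measured transcript levels in planarians after amputation, with and without RNA interference against runt-1, a transcription factor gene. Each of 12 arrays set RNA of runt-1 RNAi animals (Cy5) against RNA of unc-22 RNAi animals (Cy3), the control. There were 3 arrays for each of 4 groups: whole animals at 5 min, 9 h and 24 h after amputation, and X1 cells sorted from animals at 9 h. Between 59.2% and 83.5% of the probes were well above background in the Cy3 channel of an array, and between 57.7% and 87.4% in the Cy5 channel, and 0 probes were saturated on any array. Control-channel intensities correlated at r = 0.956 to 0.996 across probes between whole-animal arrays, at r = 0.993 to 0.994 between X1 arrays, and at r = 0.760 to 0.802 between whole-animal and X1 arrays. Probes are not independent replicates.

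The first question was how control animals changed after amputation. In unc-22 RNAi animals at 9 h, 186 probes had risen and 73 had fallen against 5 min. Of the risen probes, 78 had risen at least 2-fold and 15 at least 4-fold. The largest rises were those of SMED_05187_V2_1, which rose by a log2 value of 3.55 (SE 0.26, adjusted p = 0.000106 in limma), from 8.15 ± 0.13 to 11.71 ± 0.30 (SD, n = 3 arrays each), and of SMED_07003_V2_1, which rose 9.84-fold, a log2 value of 3.30 (SE 0.18, adjusted p = 7.83e-06). Falls were smaller. SMED_06904_V2_1 fell by 1.54 on the log2 scale (SE 0.20, adjusted p = 0.00542) and SMED_14856_V2_1 fell by 1.54 (SE 0.19, adjusted p = 0.00474). The count of 259 probes depended on single arrays, partly through the spread shared by all 12. It was 4136 without array 3 of the 5 min group and 69 without array 2. It was 65 and 37 without arrays 1 and 2 of the 9 h group, and 140, 159 and 163 without X1 arrays 1, 2 and 3.

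At 24 h, 468 probes had risen and 215 had fallen in the control animals against 5 min. SMED_02793_V2_1 rose 12.0-fold, a log2 value of 3.59 (SE 0.22, adjusted p = 1.75e-05), and SMED_05187_V2_1 rose 10.3-fold, a log2 value of 3.37 (SE 0.26, adjusted p = 0.000163). SMED_08568_V2_1 fell by 2.38 on the log2 scale (SE 0.47, adjusted p = 0.0287) and SMED_06904_V2_1 fell by 2.09 (SE 0.20, adjusted p = 0.000484). The first of these falls rested on values of 11.05 ± 1.18 at 5 min and 8.67 ± 0.42 at 24 h (SD, n = 3). Of the probes called at each time, 128 rose and 47 fell at both, and 0 moved in opposite directions. Independent lists of these sizes would share 2.31 rising and 0.416 falling probes, but these lists were not independent, since both use the same 5 min arrays. Across probes, the covariance of the log2 changes was 0.0812, against 0.0182 in simulated unchanged groups that share a simulated 5 min group (r = 0.86 against 0.50). The simulation gave a probe the same spread in every group and drew probes independently. Array 1 of the real 5 min group had the lowest array weight in the control channel, 0.17. The simulated covariance may thus be too low, and the excess cannot be read as a shared response to amputation. The median log2 change of the rising probes called at 9 h was 0.67 within slide 6 and 1.13 and 0.83 within scan sessions 1 and 2. For those called at 24 h it was 1.05 within slide 1 and 0.93 and 0.80 within the sessions. These probes were chosen on the same arrays, so the values are no independent test of a batch effect. With the scan session as a term the counts were 447 and 1054. The 24 h count was 411, 204 and 3189 without arrays 1, 2 and 3 of the 5 min group, and 135 and 173 without arrays 1 and 3 of the 24 h group. It was 413 without array 2 of the 9 h group, and 355, 374 and 407 without X1 arrays 1, 2 and 3. In fits of the compared groups' own 6 arrays the counts were 17 at 9 h and 15 at 24 h.

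X1 cells differed from whole animals at most of the probes tested. In controls at 9 h, 13990 probes (37.1%) were higher in X1 cells and 9610 (25.5%) were lower, on a scale that sets the arrays' overall distributions equal. Among these, 2268 were at least 4-fold higher and 3335 at least 4-fold lower. SMED_18434_V2_1r was 171-fold higher in X1 cells, a log2 value of 7.42 (SE 0.24, adjusted p = 4.84e-11). What this probe detects was not established, and whether it is a ribosomal RNA was not checked. SMED_35571_V2_1 had a log2 difference of 6.62 (SE 0.12, adjusted p = 7.69e-13), with 1 of its 3 whole-animal arrays well above background. SMED_01606_V2_1 had a log2 difference of -8.60 (SE 0.33, adjusted p = 1.82e-10), with 2 of its 3 X1 arrays well above background. The sizes of these last 2 differences rest partly on values near the background. SMED_01742_V2_1 was not well above background on any X1 array and was at least 360-fold lower there (adjusted p = 5.73e-13). No slide held both groups, and X1 arrays lay in scan session 2 alone. Within that session the log2 differences of the first 3 probes were 7.14, 6.53 and -8.60.

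The targeted transcript comes first in a test of an RNAi, but no probe was paired with runt-1 in the files used here, so the efficiency of the RNAi is not reported. The ratios of the arrays did not all run alike. Labels give the same dye orientation for every array, yet the log2 ratios of arrays 1 and 3 of the 5 min group correlated at r = -0.70 across probes, and those of arrays 1 and 2 of the 24 h group at r = -0.59. Within the 9 h group r ranged from 0.0044 to 0.53, and within the X1 group from 0.10 to 0.53. Directions below follow the dyes in the labels, and counts with the ratio of array 3 of the 5 min group turned are given with each comparison of ratios where they differ.

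**Figure D1:**
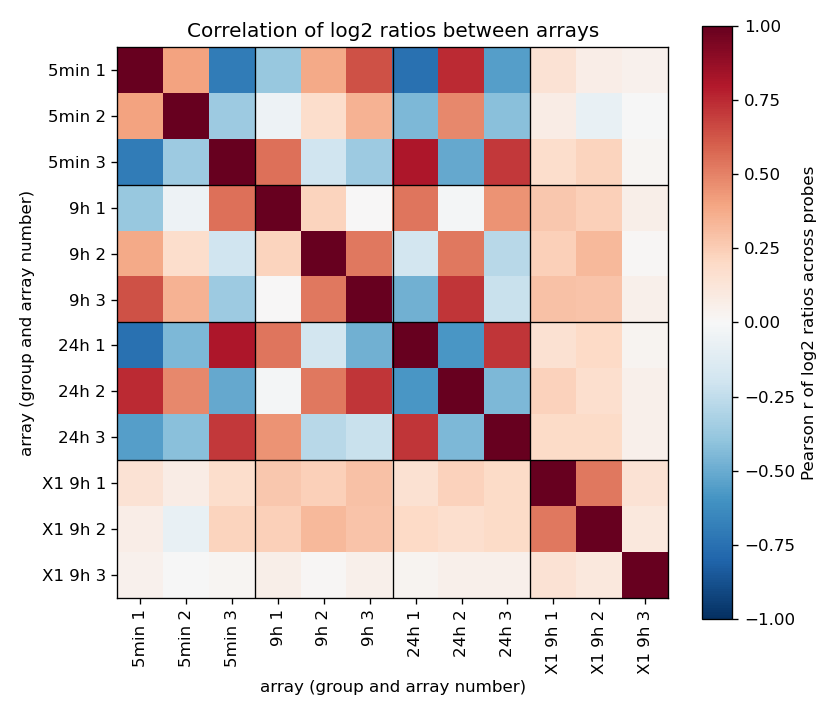
Pearson correlation, across the tested probes, of the log2 ratio of runt-1 RNAi over unc-22 RNAi between each pair of the 12 arrays, with blue below 0 and red above 0. Arrays of the 5 min and 24 h groups include pairs at r = -0.70 and r = -0.59, while X1 arrays correlate with each other at 0.10 to 0.53.

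SMED_07003_V2_1 and SMED_28642_V2_1, singled out after their values were seen, had the largest negative log2 ratios of all tested probes in whole animals at 9 h and at 24 h. It is unknown whether either probe detects the transcript that the RNAi targets, in which case its low ratio would be the knockdown itself. At 9 h the log2 ratio of SMED_07003_V2_1 was -2.58 ± 0.07 (SD, n = 3) and that of SMED_28642_V2_1 was -2.31 ± 0.19, and at 24 h they were -1.95 ± 0.28 and -1.67 ± 0.30. None of these 4 values passed the threshold in limma over all probes (adjusted p = 0.147, 0.170, 0.262 and 0.478), though each was negative on all 3 arrays. In the authors' deposited table the same probes have log2 fold changes of -2.59 and -2.43 at 9 h (adjusted p = 6.07e-07 and 1.19e-08). At 5 min their ratios were 0.37 ± 1.02 and 0.06 ± 0.28. In control animals both probes rose after amputation, SMED_28642_V2_1 by 2.38 at 9 h and by 1.91 at 24 h on the log2 scale (adjusted p = 0.00113 and 0.00355), and SMED_07003_V2_1 by 3.30 and 3.06. In the runt-1 RNAi channel the same contrasts gave 0.01 and 0.18 for SMED_28642_V2_1 (SE 0.46) and 0.35 and 0.74 for SMED_07003_V2_1 (SE 0.43), none past the threshold (lowest adjusted p = 0.683). These changes depend on array 3 of the 5 min group, whose orientation is in doubt. SMED_07003_V2_1 was at 8.09, 8.07 and 9.81 on 5 min arrays 1 to 3 in that channel, and at means of 9.01 and 9.40 at 9 h and 24 h. SMED_28642_V2_1 was at 6.93, 6.98 and 7.82, and at 7.25 and 7.42. The sequence of SMED_07003_V2_1 is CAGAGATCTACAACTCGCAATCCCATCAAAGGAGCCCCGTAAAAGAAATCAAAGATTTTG and that of SMED_28642_V2_1 is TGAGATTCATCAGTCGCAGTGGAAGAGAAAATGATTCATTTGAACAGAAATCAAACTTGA.

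**Figure D2:**
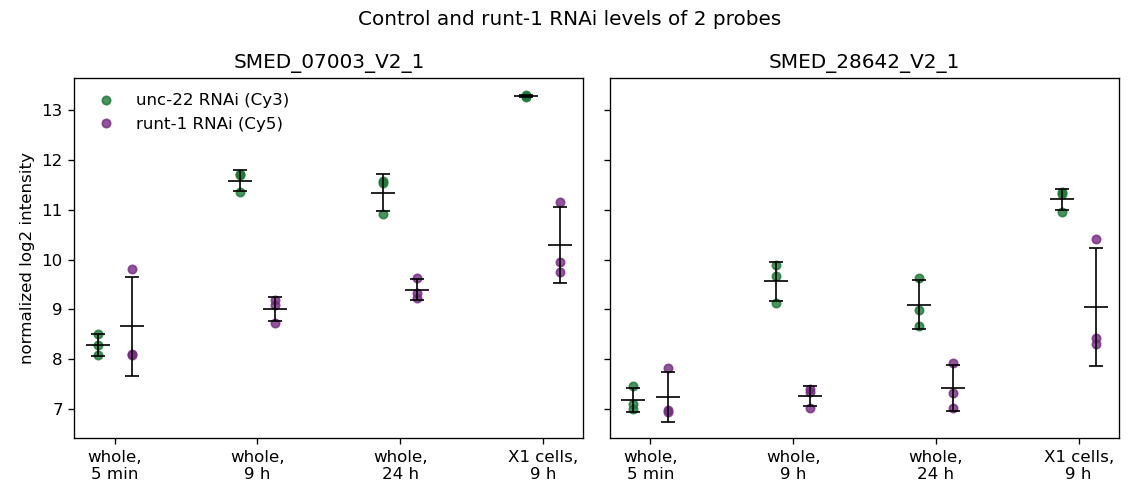
Normalized log2 intensity of 2 probes in the control channel (green) and the runt-1 RNAi channel (purple) of each array, with bars for the mean and SD of 3 arrays per group. SMED_07003_V2_1 was at 8.29 in control animals at 5 min and at 11.59 at 9 h, where the runt-1 RNAi channel was at 9.01.

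In X1 cells, the ratio of runt-1 RNAi over control passed the threshold at 16 probes, 15 higher and 1 lower. SMED_07003_V2_1 fell 7.99-fold, a log2 ratio of -2.998 ± 0.768 (SD, n = 3; adjusted p = 0.0327). SMED_01539_V2_1 rose 2.24-fold, a log2 ratio of 1.17 ± 0.17 (adjusted p = 0.0327), and SMED_00980_V2_1 rose 2.22-fold, 1.15 ± 0.05 (adjusted p = 0.0327). These 3 calls were lost under 10, 10 and 14 of 25 alternatives. SMED_00980_V2_1 had ratios above 0 on all 12 arrays, from 0.41 to 1.40 in whole animals, and the authors' deposited table gives it a log2 fold change of 0.34 in X1 cells (adjusted p = 0.232). The log2 ratios of the 15 higher probes ranged from 0.39 to 1.17. Some of them were bright: SMED_00980_V2_1, SMED_00433_V2_1 and SMED_24617_V2_1 had mean log2 intensities of 17.7, 17.3 and 17.4. SMED_00433_V2_1 was at 0.95 here and at 0.30 in the authors' deposited table. No dye swap balances a dye effect in these ratios, so the 15 cannot all be taken as effects of the RNAi. Of the 16 probes, 7 were lower and 3 higher in X1 cells than in whole animals among controls. All 16 had the same sign in whole animals at 9 h. SMED_28642_V2_1 did not pass, with a log2 ratio of -2.16 ± 1.40 (adjusted p = 0.161) and arrays at -2.88, -3.06 and -0.54. It passed under 8 of 24 alternatives, among them leaving out X1 array 3. The authors' deposited table gives it a log2 fold change of -3.18 in X1 cells (adjusted p = 8.90e-10). On X1 array 3 the ratios of several dim named probes lay close to 0. SMED_24410_V2_1 was at 0.18, 0.31 and -0.0084 on X1 arrays 1 to 3, and SMED_01065_V2_1 at 0.29, 0.35 and -0.011. Array 2 of the 5 min group, also on slide 4, had 0.0010 for SMED_07003_V2_1 and -0.011 for SMED_28642_V2_1. The cause was not tested, and these 2 arrays may understate ratios at low signal. The difference between X1 cells and whole animals at 9 h passed the threshold for 0 probes in limma, with 534 at an unadjusted p under 0.05. It passed for 7 probes, all lower, with slide as a fixed block, for 10 (7 higher, 3 lower) in a fit of the compared groups' own arrays, for 4 with array weights and for 1 without X1 array 3. Slide 3 held only X1 arrays 1 and 2, so with slide as a fixed block they do not enter this difference. Among X1 arrays the difference then rests on array 3, set against 5 min array 2 on slide 4. The count of 16 rested on the arrays that set the spread: a fit of the 3 X1 arrays alone called 481 probes (345 higher, 136 lower), the 16 among them, with the spread of those arrays only. Leaving out 1 array gave 0 probes for arrays 1 and 3 of the whole 9 h group, arrays 1, 2 and 3 of the 24 h group and arrays 1 and 2 of the X1 group. It gave 2 probes for array 2 of the whole 9 h group, and 59, 54 and 31 for arrays 1, 2 and 3 of the 5 min group. Without X1 array 3 it gave 12 probes, 5 higher and 7 lower, of which 5 were among the 16. With the 5 min array turned 8 probes passed. With processed signals 237 probes passed, 95 of them higher, and with scaling between arrays 51 passed, 13 of them higher and 0 shared with the 16. With the scan session as a term 1 remained.

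In whole animals few probes passed. At 5 min, 0 probes passed in limma and 2602 had an unadjusted p under 0.05. The highest and lowest moderated t belonged to SmWIOct06_043243, with a log2 ratio of 0.58 ± 0.11 (SD, n = 3; adjusted p = 0.115), and SMED_14138_V2_1, with -0.29 ± 0.13 (adjusted p = 0.411). Their values on array 3, 0.69 and -0.33, had the sign of arrays 1 and 2. Turning that array would bring both means nearer to no change, so their ranks depend on its orientation. With the ratio of array 3 turned, 2635 probes passed, and without that array 3073 did. At 9 h, 0 probes passed and 2470 had an unadjusted p under 0.05. The lowest moderated t belonged to SMED_01940_V2_1, with a log2 ratio of -0.73 ± 0.08, and SMED_24410_V2_1, with -1.55 ± 0.24, and the highest to SMED_00433_V2_1, with 0.84 ± 0.15, and SMED_01464_V2_1, with 1.14 ± 0.04 (adjusted p = 0.147 for each). In the authors' deposited table the last 2 have log2 fold changes of 0.26 and 0.54 (adjusted p = 0.160 and 0.0810), and SMED_00433_V2_1 had ratios above 0 on all 12 arrays. With the 5 min array turned 4 probes passed at 9 h. At 24 h, SMED_08801_V2_1 was the 1 probe past the threshold. It rose by a log2 value of 0.52 ± 0.03 (adjusted p = 0.0278), with ratios above 0 on all 12 arrays, and the call was lost under 17 of 25 alternatives, among them leaving out any array of the 9 h or 24 h group or X1 array 1 or 2, and turning the 5 min array, which gave 0 probes. The authors' deposited table gives it 0.54 (adjusted p = 0.0966). The lowest moderated t at 24 h belonged to SMED_07003_V2_1 and to SMED_01775_V2_1, with a log2 ratio of -0.26 ± 0.02 (adjusted p = 0.326). The authors' deposited table lists 457, 133, 143 and 324 probes at an adjusted p under 0.05 at 5 min, 9 h, 24 h and in X1 cells. Of these, 0, 0, 0 and 10 passed here, while 100%, 100%, 100% and 99.7% had the same sign here. Across the tested probes, log2 values in that table correlated with those here at r = 0.89, 0.95, 0.96 and 0.59. The cause of the different counts was not tested.

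The next question was whether the ratio differed between times. Between 24 h and 9 h it differed at 3 probes. SMED_24410_V2_1 had a log2 ratio of -1.55 ± 0.24 at 9 h and 1.04 ± 0.40 at 24 h (SD, n = 3), a difference of 2.59 (SE 0.27, adjusted p = 0.0362). SMED_01940_V2_1 went from -0.73 ± 0.08 to 0.63 ± 0.11, a difference of 1.36 (SE 0.12, adjusted p = 0.0165). SMED_01065_V2_1, chosen after its values were seen, went from -1.34 ± 0.20 to 1.21 ± 0.43, a difference of 2.55 (SE 0.28, adjusted p = 0.0405). With slide as a fixed block the differences were 2.77, 1.41 and 2.73 (SE 0.30, 0.18 and 0.31), but 0 probes passed. Within slide 2 they were 2.89, 1.24 and 2.65, and within slide 5 they were 2.14, 1.26 and 2.20, where the 9 h array lay at position 4 and the 24 h array at position 2 on both slides. Within scan session 1 they were 3.05, 1.33 and 2.93, and within session 2 they were 2.04, 1.32 and 2.08. Positions were the other way round for array 3 of the 9 h group (position 2) and array 1 of the 24 h group (position 4). The log2 ratios there were -1.32, -0.82 and -1.13, and 1.41, 0.75 and 1.68, so the sign followed the group at both positions. The count of 3 was 0 without array 2 of the 5 min group, any array of the 9 h group, arrays 1 and 2 of the 24 h group or X1 arrays 1 and 2, and 1 without X1 array 3. With the 5 min array turned it was 4. The calls of SMED_24410_V2_1 and SMED_01065_V2_1 were lost under 16 and 17 of 25 alternatives and that of SMED_01940_V2_1 under 14 of 24. In control animals the 3 probes rose from 5 min to 9 h, by 3.11, 1.95 and 2.85 on the log2 scale (adjusted p = 0.00191, 0.00260 and 0.00438). From 5 min to 24 h the control changes were 1.32, 1.55 and 1.24 (adjusted p = 0.0703, 0.00587 and 0.0876). In runt-1 RNAi animals the changes from 5 min to 9 h were 1.60, 1.25 and 1.42 (adjusted p = 0.0776, 0.0339 and 0.0839), and from 5 min to 24 h the probes rose by 2.40, 2.21 and 2.37 (adjusted p = 0.0102, 0.000535 and 0.00655). Their probe sequences are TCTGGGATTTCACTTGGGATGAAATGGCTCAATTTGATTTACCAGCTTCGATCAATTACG, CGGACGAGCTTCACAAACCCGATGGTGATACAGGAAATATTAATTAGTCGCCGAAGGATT and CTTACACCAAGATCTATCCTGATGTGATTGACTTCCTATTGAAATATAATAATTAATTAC in the same order.

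**Figure D3:**
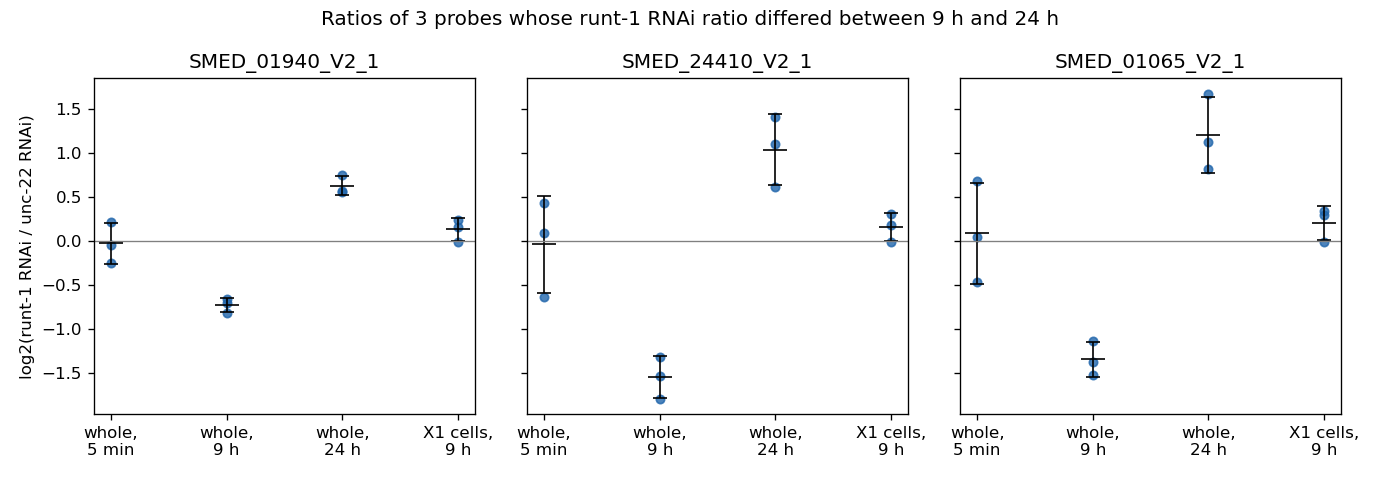
Log2 ratio of runt-1 RNAi over unc-22 RNAi for 3 probes, a point per array, with bars for the mean and SD of 3 arrays per group. All 9 h values lie below 0 and all 24 h values above 0.

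Neither 9 h against 5 min nor 24 h against 5 min gave a probe past the threshold for a difference in ratio in limma (0 and 0, with 823 and 1595 at an unadjusted p under 0.05). SMED_07003_V2_1 had a difference of -2.95 (SE 0.47) at 9 h against 5 min and of -2.32 (SE 0.47) at 24 h against 5 min (adjusted p = 1.00 and 0.633). With the 5 min array turned, 22 and 3377 probes passed, and without that array the second count was 1788.

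The rise after amputation was also followed in both channels. Of the 468 probes that rose by 24 h in control animals, 466 had the same sign in runt-1 RNAi animals, and 77 of them also passed there. Their median log2 change was 0.84 in controls and 0.38 in runt-1 RNAi animals, and 0 of them passed the test of the difference in ratio. Without array 3 of the 5 min group, 1788 of all tested probes passed that test. The counts and medians of the 468 were not recomputed without that array or with it turned. These probes were chosen on the control channel of the same arrays, which by itself makes the control change the larger. Of the 186 probes that rose by 9 h, 186 had the same sign and 55 passed in runt-1 RNAi animals, with medians of 0.94 and 0.62. Both channels were read from the same spots of the same arrays, so an effect of an array or spot can move both alike. The agreement in sign at 9 h and 24 h is therefore no independent evidence of a rise in runt-1 RNAi animals.

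**Figure D4:**
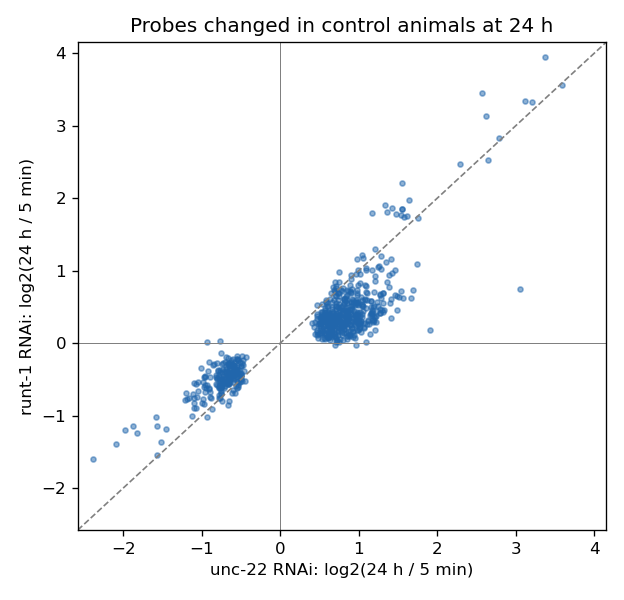
Log2 change from 5 min to 24 h in control animals (horizontal axis) and in runt-1 RNAi animals (vertical axis) for the 683 probes past the threshold in controls. The dashed line marks equal change, and most rising probes lie below it.

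For sets, the 100 wound-induced probes (higher at 24 h than at 5 min in controls) had a median log2 ratio of -0.04 in whole animals at 9 h, with 60 of 100 below 0, array medians of -0.12, 0.0092 and -0.02, and a median of 0.03 without array 2 of the 24 h group. The preset camera test gave an adjusted p of 1.62e-05 for a shift down, and adjusted p = 0.332 with an estimated correlation. Of these probes 0 passed over all probes tested, and 7 did, all lower, when adjusted over the set alone. The set made from 9 h against 5 min had a median of -0.11 at 24 h (adjusted p = 0.0266 preset and adjusted p = 0.637 with an estimated correlation), with array medians of -0.27, 0.21 and -0.11, a median of -0.22 with the 5 min array turned, and 9 passed when adjusted over the set alone (7 higher, 2 lower). The preset call was lost without array 1 or 2 of the 5 min group (adjusted p = 0.509 and 0.0840), array 1 or 2 of the 9 h group (adjusted p = 0.885 and 0.0641) or array 1 or 3 of the 24 h group (adjusted p = 0.993 and 0.191). At 5 min and in X1 cells another wound-induced set of 100 probes was used, higher at 9 h and 24 h together than at 5 min in controls. At 5 min this set had a median of 0.25 (adjusted p = 3.53e-11 preset and adjusted p = 0.332 with an estimated correlation), but it shares arrays with that ratio. Its array medians there were 0.46, 0.40 and -0.15, and its median was 0.65 with array 3 turned, 0.81 without array 3 and 0.12 without array 1. In X1 cells its median was 0.02 and its mean -0.05 (adjusted p = 0.748 preset).

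The 200 X1-enriched probes had median log2 ratios of 0.01, -0.01 and -0.03 in whole animals at 5 min, 9 h and 24 h, with adjusted p = 0.748, 0.284 and 0.0373 in the preset camera test and adjusted p = 0.584 at 24 h with an estimated correlation. Their means were 0.02, 0.0031 and -0.03. The preset call at 24 h was lost without array 1 of the 5 min group (adjusted p = 0.509), array 1 or 2 of the 9 h group (adjusted p = 0.0549 and 0.0574), array 2 of the 24 h group (adjusted p = 0.212) or X1 array 1 or 2 (adjusted p = 0.173 and 0.0694). The set passed at 9 h without array 2 of the 5 min or of the 9 h group (adjusted p = 0.0463 and 0.000831). In X1 cells their median was -0.08, with 160 of 200 below 0 (adjusted p = 1.96e-23 preset, 0.00406 with an estimated correlation, and 0.00444 in fry), and 0 passed over all probes while 19 did, all lower, when adjusted over the set alone. That set shares arrays with the ratio. When it was made from the other X1 arrays, the medians on the array left out were -0.11, -0.06 and -0.04. There 160, 142 and 159 of the 200 were below 0. Medians of all probes on these arrays were 0.0060, 0.0090 and -0.0019, with 48.0%, 47.1% and 60.4% below 0. No dye swap balances a dye effect in this ratio, so the shift cannot be assigned to the RNAi.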

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

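The tests of slide and of a dye effect below were chosen after the result was seen. The runt-1 RNAi ratio differed between 24 h and 9 h at 3 probes, found by the test of the difference itself in limma. The difference in log2 ratio was 2.55 at SMED_01065_V2_1, 2.59 at SMED_24410_V2_1 and 1.36 at SMED_01940_V2_1 (adjusted p = 0.0405, 0.0362 and 0.0165). Of the 10 splits of the 6 arrays, the real one gave 3 probes and the highest of the others 0, and the splits are too few for a share under 0.05.

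Within a slide, where an effect of that slide cancels, the smallest difference was 1.24. The probes were called on these same arrays, and their 9 h and 24 h values did not overlap. A large difference within any slide thus follows from the choice of probes, and the value is no independent test of slide. A dye effect common to all arrays cancels in the difference and so cannot make it. That 18 of 18 values had the sign of their group restates the pattern and adds nothing to this. A test with the leading residual component of the arrays was void, because the component is centred within groups and leaves the differences as they were (a ratio of 1), so that structure stays open. A fixed slide block ended the calls, with a difference of 1.36 (SE 0.12) becoming 1.41 (SE 0.18) at SMED_01940_V2_1, where the SE grew and the difference did not shrink. A different time course in runt-1 RNAi animals is left as an open hypothesis. A rise that only comes later was not shown: in the runt-1 RNAi channel the changes at 9 h against 5 min were 1.42, 1.60 and 1.25 in the same order, and SMED_01940_V2_1 passed there (adjusted p = 0.0339) and in controls at 24 h (1.55, adjusted p = 0.00587).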

How the results depend on the processing

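Alternatives added after the data were seen were the turned array, the component covariate, the runt-1 RNAi channel and those of the probe sets; the others were fixed before. Counts below are in the order 5 min, 9 h, 24 h, X1 for ratios; 9 h and 24 h for controls against 5 min. The count of X1 against whole animals stayed within 1.5 times 23600 under every alternative run.

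Without background correction the ratio counts were 52, 35, 27 and 142, the control counts 1912 and 1985, and 24 h against 9 h gave 0. Processed signals gave 37, 21, 14 and 237, 74 and 330, and 0. An offset of 16 gave 0 at 24 h and 144 and 368 in controls. Scaling between arrays gave 2 at 9 h, 0 at 24 h, 51 in X1 and 0 for 24 h against 9 h, with quantile counts of 592 and 1072 in controls. Rising probes were then 59.6% and 58.9% of these calls. The stricter filter gave 0 at 24 h. A random slide block gave 41 in X1 and 1 for 24 h against 9 h, and a fixed slide block 0 for the latter and 7 for X1 against whole animals. Among X1 arrays, only array 3 enters that last count. A session term gave 0 at 24 h, 1 in X1, 0 for 24 h against 9 h, and 447 and 1054. Fits of the compared groups alone gave 36, 0 and 481 at 9 h, 24 h and in X1, 0 for 24 h against 9 h, 10 for X1 against whole animals, and 17 and 15. Array weights gave 6745, 68, 8715 and 489, differences of 3073, 11702, 723 and 4 (9 h and 24 h against 5 min, 24 h against 9 h, X1 against whole animals), and 2538 and 1875. For ratios, 5 min arrays 1 to 3 had weights of 0.17, 3.74 and 0.20. The weighted 5 min means thus rest mostly on array 2, which may understate ratios at low signal. The authors' table gave 457, 133, 143 and 324. The component covariate gave 4322, 462, 3440 and 95 and differences of 7246, 226 and 2; these are too high, since it was taken from the same residuals. The turned array gave 2635, 4, 0 and 8, and differences of 22 and 3377. The excess under the covariate follows from how it was made, and for the other alternatives the cause was not tested.

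Leaving out 1 array gave ranges of 0 to 3073, 0 to 6, 0 to 6 and 0 to 59 for ratios. Differences ranged over 0 to 1, 0 to 1788, 0 to 3 and 0 to 1, and controls over 37 to 4136, 135 to 3189 and 21815 to 25084 (X1). Set medians in the X1-enriched set ranged from 0.0020 to 0.033 at 5 min, -0.027 to 0.018 at 9 h, -0.036 to 0.0015 at 24 h and -0.10 to -0.064 in X1. In the wound-induced sets they ranged from 0.12 to 0.81, -0.056 to 0.028, -0.21 to 0.0067 and -0.0090 to 0.026. Values of opposite sign were 0.0015 (X1-enriched, 24 h, without 5 min array 1), 0.0091 and 0.018 (X1-enriched, 9 h, without 9 h array 3 and 24 h array 1), 0.0067 (wound-induced, 24 h, without 24 h array 1), 0.028 (wound-induced, 9 h, without 24 h array 2), and -0.0044, -0.0090 and -0.0087 (wound-induced, X1, without 5 min array 3, 9 h array 3 and X1 array 1).

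The X1-enriched median at 5 min was -0.022 without background correction, now past the threshold (adjusted p = 0.00791), and -0.043 with processed signals (adjusted p = 0.0865); at 9 h it was -0.032 and -0.085, both now past it. It was -0.025 at 24 h with the turned array, no longer past it. The wound-induced median in X1 was -0.00091 with processed signals and -0.021 with the turned array. The X1 against whole-animal difference of SMED_28642_V2_1 was -0.75 without background correction, -0.69 with processed signals, -2.53 with scaling, -0.049 with a random slide block and -0.66 without X1 array 3, where leaving out 1 array gave up to 0.60. Its 5 min ratio was -0.32 with processed signals, -0.092 without array 3 (up to 0.18 without another) and -0.18 with it turned. SMED_07003_V2_1 had 1.06 for X1 against whole animals with a fixed slide block, where only X1 array 3 enters this difference. At 5 min it had -0.21 and -0.65 without array 3 (up to 0.76 without another) and with it turned. The cause was not tested.

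No paired analysis was possible because the labels number replicates 1 to 3 per sample but tie no array to a number. Gene list and probe-per-gene alternatives were not run, since no probe has a gene name. The authors' table exists for ratios only, and a fixed slide block was fitted for differences only. Signal limits the values: 57.7% to 87.4% of probes per channel were well above background.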

Other observations

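The comparison of wound-called probes with X1 cells, the count of probes with 1 sign on all arrays, and the tests of dye exchange, dye effect, array position, scan session, X1 share and low signal below were chosen after results were seen. Probes that rose after amputation in controls tended to be higher in X1 cells, measured on arrays outside the contrast that called them. The 468 probes that rose by 24 h had a median log2 difference of 1.20 between X1 cells and whole animals at 9 h, against -0.37 to 0.04 in the central range of 10000 random lists of like intensity. Of these probes 69.4% were higher in X1 cells, against 58.6% of all probes. The 215 that fell by 24 h had a median of -2.24. For the 186 that rose by 9 h the median against whole animals at 24 h was 0.54, with 61.8% higher in X1 cells against 57.9% of all probes, and for the 73 that fell it was -1.71.

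On all 12 arrays 434 probes had a log2 ratio above 0 and 200 below 0, where independent signs would give 9.18 of each. A dye effect common to all arrays may contribute, since no array had the dyes swapped. For SMED_28642_V2_1 and SMED_07003_V2_1 the lower of the mean log2 ratios at 5 min was 0.060, which does not settle this: signal at 5 min was low, and with array 3 turned the means were -0.18 and -0.65. Of 3314 pairs of a probe and its reverse complement, 803 had both, 1553 only the forward and 145 only the reverse probe well above background on all arrays in the control channel.

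Ratios of arrays within a group ran in opposite directions, and the leading residual component held 65.6% of the residual variance. An exchange of the dyes of array 3 of the 5 min group cannot explain the 24 h arrays, where the lowest r was -0.59. For the 5 min arrays it stays open. That the turned array 3 correlated with array 1 at 0.70 follows from the turning itself and supports nothing, and SMED_07003_V2_1 was then at -1.53 on array 3 and at -0.41 and 0.0010 on arrays 1 and 2. Scan session is argued against, as arrays of 1 group in 1 session had r down to -0.59 at 24 h and -0.36 at 5 min. Position on the slide stays open. Arrays 2 and 3 of the 24 h group shared a position at r = -0.45, but no other such pair was opposed. Arrays 1 of the 5 min group and 2 of the 24 h group, at position 2, had loadings of 0.57 and 0.43 on the component, and arrays 3 of the 5 min group and 1 of the 24 h group, at position 4, had -0.58 and -0.29. Arrays 3 and 1 of the 9 h group, at positions 2 and 4, had 0.13 and -0.20. Array 3 of the 24 h group, at position 2, had -0.14 and array 2 of the 9 h group, at position 4, had 0.063, against this pattern. Array 2 of the 5 min group, at position 2, had 0.0091. A difference in the share of X1 cells is argued against by r = -0.066 between the component and the X1 contrast, and noise of single spots by r = 0.99 between 202 pairs of probes with 1 sequence. RNA quality or differences between animals could also contribute and were not tested.

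SMED_07003_V2_1 and SMED_28642_V2_1 had low ratios at 9 h and 24 h and not at 5 min. Fewer X1 cells in the runt-1 RNAi animals are argued against as the cause, since the X1-enriched probes had a median log2 ratio of -0.0068 at 9 h (-0.085 with processed signals). Low signal at 5 min may hide a fall of SMED_28642_V2_1, whose control level lay 0.82 above the lowest signal well above background on the log2 scale. For SMED_07003_V2_1 it lay 1.92 above, which leaves this open. A dependence of the wound-induced rise of both probes on runt-1 stays open as a hypothesis. So does the knockdown itself, for a probe that detects the targeted transcript, which could not be checked without gene names.

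Turning the sign of single arrays gave 4 patterns per ratio, too few for a share under 0.05. The measured pattern gave 0, 0, 1 and 16 probes at 5 min, 9 h, 24 h and in X1 cells, and the highest other 2635, 0, 0 and 0, with 4, 4, 1 and 1 patterns giving as many. The comparisons of 3 arrays with 3 have 10 splits, also too few. The differences 9 h against 5 min, 24 h against 5 min and X1 against whole animals each gave 0, as few as any of the 10, and the highest other splits gave 0, 17997 and 0. The split with 17997 set 24 h arrays 1 and 3 with 5 min array 3 against the rest, which points to a structure of the arrays. In controls the real splits gave 259, 683 and 23600 probes and the highest others 0, 1 and 0, with 1 split giving as many in each.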
